A study of Mus musculus with 6 samples.

How the data were processed

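Bone RNA of GH-deficient lit/lit mice, pooled from 2 animals per sample, was compared between GH and PBS injection on 6 two-colour arrays, 3 at 6 hours and 3 at 24 hours. Per the labels' protocols, total RNA was linearly amplified from an oligo(dT) primer carrying a T7 promoter, and the cRNA was labelled with Cy5 (GH) or Cy3 (PBS); no dye swap was labelled. Time, treatment and replicate number were taken from the labels. The animals of each pool were separate by the design text, so the spread between arrays holds both animal and technical variation.

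The authors deposited 1 log2 ratio per array and row, 21446 rows in all, of which 1257 held no value and 17414 held a value on all 6 arrays. In 100% of the deposited values 2 to the power of the value was a ratio with 2 decimals, within 0.01 of a hundredth plus 0.0001 of the ratio, so the values are log2 of rounded linear ratios. The medians of the 6 arrays, in replicate order, were -0.0145, 0.0144, 0.0144, 0, 0 and 0.0286, so each array was centred near 0 by a method that is not given in the sources used here. The SDs were 0.466, 0.731, 0.693, 0.767, 0.676 and 0.913, so the scale had not been made equal. Normalization, scale, flagging and extraction software are not given in the sources used here, no channel intensities were used here, and signal over background is therefore unknown. The direction GH over PBS is likely, from the dyes and channel order in the labels; the value table does not state it.

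Of the rows, 11813 carried 1 gene symbol, 559 several and 9074 none in the platform annotation. An identifier in the mouse gene table of assembly GRCm38.p6 was found for 11782 of the rows with 1 symbol and changed 0 symbols; no coordinates were used. Rows of 1 symbol were averaged per gene, and rows with no or several symbols stayed single and unnamed. A feature entered with a value on at least 2 arrays of each time, which left 16678 features (8803 named, 7875 not), 2164 of them averaged over at least 2 rows. Different rows of a gene often disagreed, as the report shows.

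Tests used limma 3.58.1 in R 4.3.3. The functions lmFit and eBayes fitted 1 mean per time to all 6 arrays, giving 4 residual degrees of freedom for a complete feature, with a prior of 2.51 degrees of freedom and a prior SD of 0.280. Each time's mean, the mean of both and the difference were tested against 0, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. All tests were two-sided. Errors are limma's moderated standard errors unless called SD.

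The named genes, the gene lists, the main tests and the alternatives were fixed before the data were examined, except where the closing section says otherwise. For each comparison the rule took the 10 largest rises and the 10 largest falls among named genes past the threshold with the same sign on every array compared, or, where fewer than 5 passed, 5 per direction with the smallest p as values. It added 12 genes chosen beforehand, passed or not (3 of them were not measured under 1 gene name), and up to 4 members of each list described, those with the smallest p. Whether the choice of the 12 genes and of the lists was independent of earlier reports on such mice is not known. The rule skipped clone names and predicted genes. Of 32 lists of pathway genes and cell type markers, with 859 genes, 28 had at least 5 measured members and were tested; STAT5-induced GH targets, chondrocyte, T and NK, and megakaryocyte markers had 4 each and were not. List tests used limma's cameraPR with a preset correlation of 0.01 on moderated t statistics turned into z scores, because camera takes no missing values. An estimated correlation and fry were run on the 15131 complete features as alternatives. These held fewer than 5 of the T-box members, so the T-box values of both alternatives do not test the whole list. The list of both times together was described by counts of members only.

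The script was tested on simulated ratios for the 16678 features with known changes. Of changes of 1 on the log2 scale it recovered 44.8% at 6 hours, 56.7% at 24 hours, 92.5% over both times and 11.9% in the difference. Of changes of 2 it recovered 97.0%, 97.0%, 98.5% and 71.2%, and of changes of 0.5 it recovered 0%, 2.24%, 7.46% and 0%. In the difference, both of 2 lists shifted by 0.5 were called and 0 of the other 26. The simulated noise was independent between features and of equal spread on all arrays, and few features were changed. The measured lists had estimated correlations of up to 0.603 (muscle markers). These rates therefore need not hold for the measured ratios, and the list check says nothing about lists with correlated members.

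Alternatives were centring on the median, scaling to 1 median absolute deviation, quantile normalization, each probe alone, other rules for missing values, exact zeros set to missing, robust empirical Bayes, array weights, each time fitted alone, the scan file prefix as a covariate, each replicate left out in turn, an adjusted p of 0.1, and a fold of at least 1.5. The prefix (A for 4 scans, B for replicates 4 and 6) comes from the labels and may mark a scan batch; all 6-hour scans have prefix A, and with it as a covariate replicate 5 alone sets the 24-hour ratio wherever it has a value. Scans of prefix A alone were added after seeing the data. Probe pairs took the first 2 rows of a gene that shared no accession, with 1000 bootstrap draws of genes for the interval.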

Results

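Bone was collected from C57BL/6J-Ghrhr<lit> (lit/lit) mice, whose mutated receptor for growth hormone-releasing hormone leaves them deficient in growth hormone (GH). The animals were 4 weeks old and received a single subcutaneous injection of GH at 4 mg per kg or of phosphate-buffered saline (PBS). Bone RNA was taken 6 or 24 hours later, and RNA of 2 animals was pooled for each sample. Each of 6 two-colour arrays compared a GH pool labelled with Cy5 with a PBS pool labelled with Cy3, with 3 arrays at 6 hours (replicates 1 to 3) and 3 arrays at 24 hours (replicates 4 to 6). The arrays held between 18302 (replicate 1) and 19961 (replicate 3) values, and the number of arrays limits the precision of what follows. Ratios are given as log2 of GH over PBS. This direction is likely rather than stated. The labels put GH in Cy5, the first channel, and name each sample for GH. No array had swapped dyes, so a gene-specific dye effect adds to every GH over PBS ratio at a single time, while one shared by all arrays cancels in the difference between the times.

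The spread of the log2 ratios differed between arrays, from an SD of 0.466 on replicate 1 to 0.913 on replicate 6. Replicate 1 correlated with the other 5 arrays at r = 0.231 to 0.364 over features, while the 10 other pairs lay between 0.564 and 0.821. Genes are not independent replicates, so these coefficients describe the profiles only. Without replicate 1 the mean r was 0.713 over 6 pairs from different times and 0.668 over 4 pairs from the same time.

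**Figure D1:**
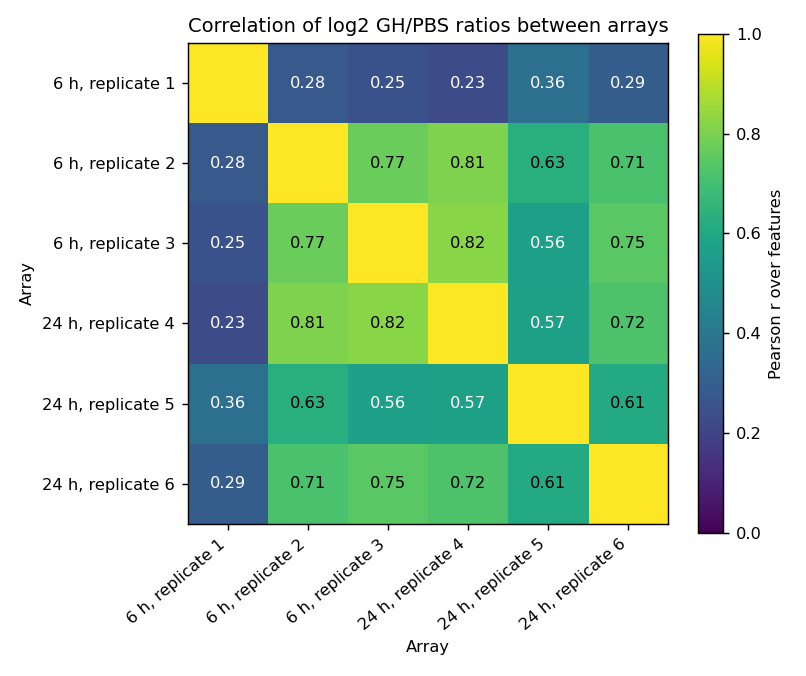
Pearson correlation (colour scale, 0 to 1, and number in each cell) of log2 GH over PBS ratios over features between each pair of the 6 arrays, labelled by time and replicate. Replicate 1 lies between 0.231 and 0.364 with every other array, and the remaining pairs between 0.564 and 0.821.

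The first comparison asked which genes differed between GH and PBS bone at 6 hours. Here and below, a rise or fall is that of the rows annotated with a gene's name. Different probes of a gene hardly correlated (r = 0.0286 over 2043 genes, described below), and no dyes were swapped. These values alone therefore do not establish a change in the named gene's transcript. Apela, which encodes a peptide ligand of the apelin receptor, rose 4.55-fold (log2 ratio 2.19 ± 0.20, SE, n = 3 arrays, adjusted p = 0.0261). Alg11, a mannosyltransferase of N-glycan assembly, rose 4.04-fold (2.01 ± 0.11, adjusted p = 0.0146). Ctnnd2 of the delta-catenin family, Ttll10 of the tubulin ligase family, Taf4b, a subunit of the transcription factor TFIID, and the carboxylesterase gene Ces1b rose by 1.72 to 1.75 on the log2 scale. Megf6, Ksr1, a scaffold of the Ras to MAP kinase pathway, Klhl34 and Spata1 rose by 1.60 to 1.68, with values on 2 arrays for Taf4b and Spata1. Scin, which encodes an actin-severing protein, showed the largest fall among genes past the threshold, clone names left aside, 3.31-fold (-1.73 ± 0.16, adjusted p = 0.0261). Caskin2, the ciliary gene Cfap44, the very long-chain acyl-CoA synthetase gene Slc27a2 and Zswim7 had log2 ratios of -1.63 to -1.45 and also passed. So did the cohesin acetyltransferase gene Esco1, Tdrd9, Ap3b2, Atpsckmt and the RNA polymerase III subunit gene Polr3f (-1.31 to -1.20). Among 16678 features tested with limma, 603 (3.62%) passed an adjusted p of 0.05 at 6 hours, 486 higher and 117 lower with GH, and 186 of them had a single gene name. The spread behind these calls and standard errors was estimated from the arrays of both times. With 6 hours fitted alone 0 passed (4287 at an unadjusted p under 0.05 in limma).

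Of the genes named in advance, only Tbx3, a T-box transcription factor, rose at 6 hours (1.11 ± 0.18, 2.16-fold, adjusted p = 0.0386). Cish, a STAT5-induced inhibitor of cytokine signalling, had a log2 ratio of 0.49 ± 0.16 (adjusted p = 0.114). Those of Igfbp3, the main carrier of IGF-1 in serum, of Igfbp5 and of the immediate-early gene Fos were 0.45 ± 0.13 (0.0928), 0.37 ± 0.13 (0.147) and 0.46 ± 0.17 (0.146). Socs3 (-0.12 ± 0.14, adjusted p = 0.592), Ghr (-0.25 ± 0.15, 0.322) and the transcriptional repressor gene Bcl6 (-0.03 ± 0.18, 0.935) did not pass. Igf1, the gene of the main GH-dependent growth factor, averaged 0.39 ± 0.23 (adjusted p = 0.313) over its 3 rows, which disagreed. Tested alone, row 2 of Igf1 rose 2.60-fold at 6 hours (1.38 ± 0.17, adjusted p = 0.0303) and lay between 0.99 and 1.64 on the 6 arrays. Row 1 had -0.36 ± 0.23 and row 3 had 0.16 ± 0.35. Igfals, Socs2 and Bglap were not measured under a single gene name.

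**Figure D2:**
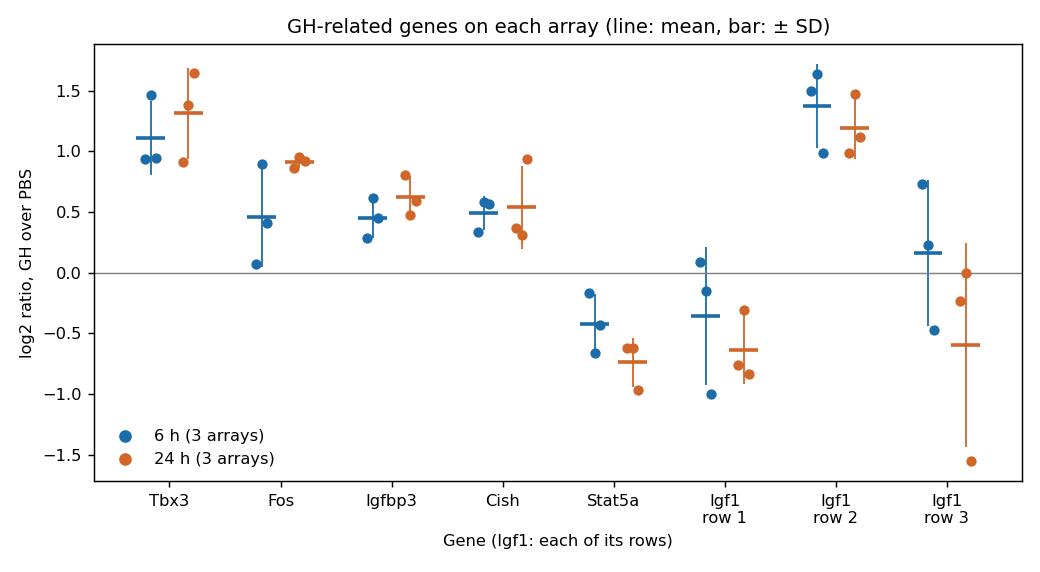
Log2 GH over PBS ratio (vertical axis) of Tbx3, Fos, Igfbp3, Cish and Stat5a and of each of the 3 rows of Igf1 on each array; points are arrays, 3 at 6 hours (blue) and 3 at 24 hours (orange), short lines are means and bars are ± SD. Row 2 of Igf1 lies between 0.99 and 1.64 on all arrays, while rows 1 and 3 lie between -1.56 and 0.73.

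At 6 hours 2 of 28 gene lists shifted against all other features by camera. The T-box transcription factors were higher (mean log2 ratio 0.77 over 5 measured members, all above 0, adjusted p = 0.0217, or 0.877 with an estimated correlation). The latter value used complete features only, fewer than 5 of these members, so it does not test the whole list. Tbx3 rose, Tbx19 (0.89), Tbx20 (0.83), Tbx15 (0.47) and 1 other member did not pass, and 3 rose when adjusted over the list alone. The skeletal muscle markers were also higher (mean 0.49, 14 of 15 above 0, adjusted p = 0.0217; adjusted p = 0.877 with an estimated correlation), with 0 of its members past limma's threshold over all features or adjusted over the list alone. The skeletal actin gene Acta1 had 0.88, the myoglobin gene Mb 0.76, Casq1, the calcium buffer of the muscle store, 0.80 and Actn2 0.84. Beside them, the neutrophil lineage markers averaged -0.54, 0 of 11 above 0 (adjusted p = 0.0524; adjusted p = 0.877 with an estimated correlation). The remaining 25 tested lists had adjusted p between 0.0965 and 0.996, and single members of 4 of them rose. These were Wnt5a (0.90) and the Wnt antagonist gene Dkk2 (1.56) among 18 Wnt pathway genes and the activin receptor gene Acvr1 (1.15) among 27 BMP and TGF-beta genes. The others were the peroxisomal enzyme gene Ehhadh (0.87) among 17 fatty acid oxidation genes and Blnk (0.94), an adaptor of the B cell receptor, among 11 B lineage markers. Adjusted over the list alone, 2, 1, 2 and 1 members of these 4 lists rose. By fry, which does not compare a list with other genes, the IGF system and the Wnt pathway also passed (both adjusted p = 0.0406, with up to 0.877 over all alternatives).

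The 6-hour count was 1501 without replicate 1, 0 without replicate 2, 3 or 4 (1923, 2018 and 3883 features at an unadjusted p under 0.05 in limma) and 88 without replicate 6, when Tbx3 also missed the threshold (1.11, adjusted p = 0.0557). After quantile normalization it was 1964 (1354 higher, 610 lower). The muscle list missed the threshold without replicate 3 (mean 0.28, adjusted p = 0.102, with 0.00260 to 0.877 over all alternatives). Without replicate 1 the neutrophil (-0.89, 0.00317), cell cycle (-0.34, 0.00317), ribosomal (-0.19, 0.0363) and erythroid lists (-0.31, 0.0363) passed as lower, while without replicate 3 their means were -0.25, -0.017, 0.042 and -0.059 and they did not pass. The neutrophil list also passed without replicate 4 (-0.54, 0.0324), and oxidative phosphorylation passed without replicate 2 (0.14, 0.0223). Over all alternatives the adjusted p of these 5 lists reached values between 0.877 and 0.984. The T-box list was not tested without replicate 1, 2, 3, 4 or 6, when fewer than 5 members were measured, and missed the threshold with array weights (0.76, 0.0654, with 0.00536 to 0.877 over all alternatives). Both ends of that range come from fry and the estimated correlation, which used fewer than 5 members.

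At 24 hours the largest rises were those of Klhl32 (2.34 ± 0.44, SE, n = 2 arrays, 5.05-fold, adjusted p = 0.0252), Alg11 (2.34 ± 0.11, n = 3, 5.05-fold, adjusted p = 0.00566) and Apela (2.17 ± 0.20, n = 3, 4.51-fold, adjusted p = 0.00821). The zinc finger gene Zfp81, the RNA-binding protein gene Rbm48, Ctnnd2 and Ttll10 rose by 1.99 to 2.10, on the log2 scale. Fermt1, a kindlin that activates integrins, Megf6 and the atypical MAP kinase gene Mapk4 rose by 1.92 to 1.97. Zbtb33, which encodes the methyl-CpG-binding repressor Kaiso, fell 7.24-fold (-2.86 ± 0.35, n = 3, adjusted p = 0.00878). Arvcf of the p120-catenin family, Atpsckmt, Myef2 and Smad9, a signal transducer of BMP receptors, had log2 ratios of -2.73 to -2.57 and passed. So did Mocos, Map3k6, the phosphoinositide 3-kinase subunit genes Pik3r3 and Pik3cb, and Cbx3, which encodes a heterochromatin protein (-2.56 to -2.53). Atpsckmt and Mocos had values on 2 arrays at 24 hours. In all, 3444 of 16678 features passed (20.65%), 2007 higher and 1437 lower, 1521 of them with a single gene name. Counts of list members at 24 hours, given below, must be read against this share.

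Tbx3 rose at 24 hours (1.31 ± 0.18, 2.49-fold, adjusted p = 0.0112), as did Fos (0.91 ± 0.17, 1.88-fold, 0.0192) and Igfbp3 (0.63 ± 0.13, 1.54-fold, 0.0230). Cish had 0.54 ± 0.16 (adjusted p = 0.0540), Socs3 0.22 ± 0.14 (0.263), Ghr -0.24 ± 0.15 (0.260), Bcl6 0.27 ± 0.18 (0.302), Igfbp5 0.11 ± 0.13 (0.556) and the Igf1 mean -0.01 ± 0.23 (0.972). Row 2 of Igf1 again rose (1.19 ± 0.17, 2.29-fold, adjusted p = 0.0123), and rows 1 and 3 had -0.63 ± 0.23 and -0.60 ± 0.35. Of the 11 measured components of GH receptor signalling 1 fell, also when adjusted over the list alone. This was Stat5a, a transcription factor that GH activates (-0.74 ± 0.14, adjusted p = 0.0215). The kinase gene Jak2 had -0.57 and Stat3 had 0.50, and neither passed. Of 9 measured genes of the IGF system 2 rose, Igf2 (0.71) and Igfbp3, and 1 fell, Irs1 (-0.59), an adaptor of the insulin and IGF-1 receptors. Adjusted over the list alone 2 rose and 2 fell. Among 16 immediate-early genes Fos and Ier3 (0.76) rose, and 1 did when adjusted over the list alone. None of these 3 lists shifted as a whole at 24 hours (adjusted p = 0.945, 0.942 and 0.945).

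Lower lists at 24 hours were those of the neutrophil lineage and of the endoplasmic reticulum. Of 11 measured neutrophil markers 4 fell and 7 did not pass (5 fell adjusted over the list alone). Those that fell were the granule protein genes Mpo (-0.89 ± 0.13) and Lcn2 (-1.44 ± 0.37), and Ms4a3 (-1.30 ± 0.28) and Cd177 (-1.43 ± 0.37). The list mean was -1.0 (adjusted p = 0.00608; adjusted p = 0.948 with an estimated correlation). Of 18 chaperones of the endoplasmic reticulum 6 fell and 12 did not pass (8 fell adjusted over the list alone). Among those that fell were Hyou1 (-0.61 ± 0.11), Dnajc3 (-1.39 ± 0.28), the calnexin gene Canx (-0.57 ± 0.14) and Dnajb9 (-0.43 ± 0.11), and the list mean was -0.41 (adjusted p = 0.0206; adjusted p = 0.948 with an estimated correlation). The T-box list stayed higher by camera, with a mean of 0.93 and 5 of 5 members above 0 (adjusted p = 0.0444, or 0.948 with an estimated correlation). The latter value again rests on fewer than 5 members. Tbx3, Tbx19 (1.36) and Tbx20 (1.18) rose, also when adjusted over the list alone, and Tbx15 had 0.35. Muscle markers averaged 0.36 beside them, 14 of 15 above 0 (adjusted p = 0.154).

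Lists on bone and its matrix did not pass as a whole at 24 hours but held single genes that moved. Over all features 20.65% passed at 24 hours, and the member counts were not tested against that share. Of 33 matrix and remodelling genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, list adjusted p = 0.161). The collagen gene Col12a1 (0.81), the lysyl hydroxylase gene Plod1 (0.96) and the collagen-binding proteoglycan gene Fmod (1.00) rose and the aggrecan-cleaving protease gene Adamts5 (-1.62) fell. Of 12 osteoclast-regulating signals 3 rose and 1 fell, with the same numbers adjusted over the list alone (list adjusted p = 0.690). The cytokine genes Il1a (0.76) and Il1b (0.87) and Tnfrsf11b (0.91), which encodes the RANKL decoy osteoprotegerin, rose and Sema3a (-1.09) fell. Among 18 Wnt pathway genes Wnt5a (1.02) and Dkk2 (1.42) rose and the antagonist genes Frzb (-0.84) and Nkd1 (-1.53) fell, with 2 and 2 adjusted over the list alone (list adjusted p = 0.523). Among 12 osteoblast markers 2 rose, Msx2 (1.33) and Col5a3 (0.67), also adjusted over the list alone (list adjusted p = 0.950). Among 9 osteoclast markers the calcitonin receptor gene Calcr (1.17) rose and the protease gene Mmp9 (-0.44) fell, with 1 and 1 adjusted over the list alone (list adjusted p = 0.945). The 25 lists that did not shift had adjusted p between 0.154 and 0.984.

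The 24-hour count was 1984, 1804, 831 and 0 without replicates 2, 3, 4 and 6 (4124 features at an unadjusted p under 0.05 in limma without replicate 6), and without replicate 4 Fos (0.94, adjusted p = 0.0708) and Igfbp3 (0.53, 0.0966) also missed the threshold. It was 32 with the scan file prefix as a covariate, a label that sets replicates 4 and 6 apart, so that replicate 5 alone sets the 24-hour ratio wherever it has a value. With that covariate the neutrophil mean was -0.60 (adjusted p = 0.152, with 0.00283 to 0.948 over all alternatives), the chaperone mean -0.36 (0.0858, with 0.00766 to 0.948) and the T-box mean 0.80 (0.0757, with 0.00494 to 0.948). The T-box call also ended when the arrays were scaled to 1 median absolute deviation (0.78, 0.0696) or quantile-normalized (0.82, 0.0573), or had weights (0.94, 0.0528). The muscle list passed without replicate 3 (0.36, 0.0480) or 6 (0.44, 0.0440, with up to 0.948 over all alternatives), but its mean was 0.15 without replicate 4 and 0.11 with the prefix (0.909). The matrix list passed without replicate 6 (0.27, 0.0208, with up to 0.948), and its mean was 0.10 without replicate 4 (0.485).

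**Figure D3:**
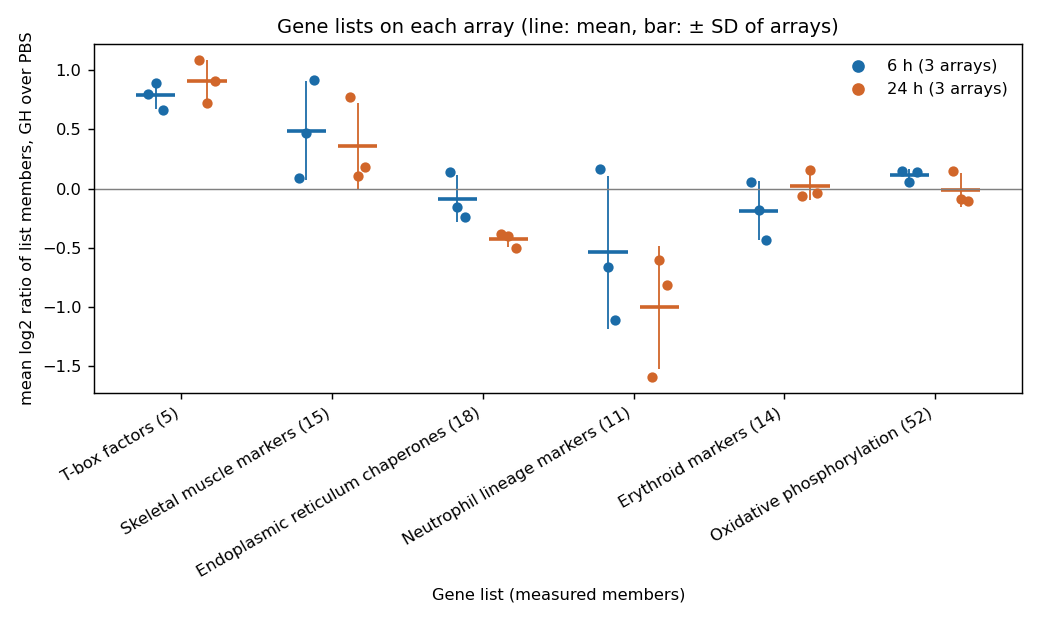
Mean log2 GH over PBS ratio of the measured members (number in parentheses) of 6 gene lists on each array; points are arrays, 3 at 6 hours (blue) and 3 at 24 hours (orange), short lines are means and bars ± SD over arrays. The neutrophil mean reaches 0.16 on replicate 1 and -1.59 on replicate 4, and the T-box mean lies between 0.67 and 1.09 on all 6 arrays.

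Over both times together, which the study counted as 6 replicates, the genes with the largest rises were Apela (2.18 ± 0.14, SE, n = 6 arrays, 4.53-fold, adjusted p = 0.00195) and Alg11 (2.17 ± 0.08, 4.52-fold, adjusted p = 0.000957). Fermt1, Ctnnd2, Ttll10, Megf6, the neurotensin gene Nts (n = 5), Zfp81, Ces1b and Fhl5 (n = 5) rose by 1.75 to 2.09. The largest falls were those of Smad9 (-2.42 ± 0.34, 5.36-fold, adjusted p = 0.00559), the RNA-editing enzyme gene Adar (-2.16 ± 0.49, n = 4) and the spliceosomal gene Snrpe (-2.14 ± 0.43). Arvcf, Zfp280b, Atpsckmt (n = 5), the kinase gene Cdc7 of DNA replication, the autophagy gene Atg2b, Slc27a2 (n = 5) and Pik3r3 had -2.12 to -1.81 and passed. Tbx3 (1.21 ± 0.13, adjusted p = 0.00304), Fos (0.69 ± 0.12, 0.00914), Igfbp3 (0.54 ± 0.09, 0.00825) and Cish (0.52 ± 0.11, 0.0160) rose, and Stat5a fell by 0.58 (0.00961). Igf1 (0.19 ± 0.16, adjusted p = 0.377), Socs3 (0.05 ± 0.10, 0.712), Ghr (-0.25 ± 0.11, 0.109), Bcl6 (0.12 ± 0.13, 0.484) and Igfbp5 (0.24 ± 0.09, 0.0892) did not pass. With each row tested by itself, row 2 of Igf1 rose (1.28 ± 0.12, adjusted p = 0.00263). Rows 1 and 3 lay on the other side of 0, at -0.49 ± 0.16 (0.0548) and -0.22 ± 0.25 (0.507), and did not pass. Over all features 35.5% passed over both times, and the following member counts were not tested against that share. Of 33 matrix genes 13 rose and 3 fell, and of 27 BMP and TGF-beta genes 3 rose and 7 fell, with the same numbers adjusted over the list alone. Acvr1 (1.28) and Smad5 (0.69) rose and Bmp2 (-0.40) and Tgfbr2 (-0.70) fell. Of 5 T-box genes 4 rose (4 adjusted over the list alone) and of 11 neutrophil markers 5 fell (9 adjusted over the list alone). Of 15 muscle markers 15 lay above 0 and 3 rose (0 adjusted over the list alone).

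In all 5914 features passed over both times, 3212 higher and 2702 lower. Without replicates 2, 3, 4 and 6 the count was 2247, 2192, 3485 and 3334, and Cish missed the threshold without replicates 2 (0.49, adjusted p = 0.0633) and 3 (0.50, 0.0616). With the scan file prefix as a covariate, which leaves replicate 5 alone to set the 24-hour ratio wherever it has a value, the count was 1393.

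The test of the difference between the times passed no feature (0 of 16678 in limma, 506 at an unadjusted p under 0.05, smallest adjusted p = 0.982). The measured arrays of the 2 times did not overlap for 1579 features, 9.47% of those tested. Chance gives 10% for features with a value on every array, 15131 of those tested, and more for the others. Traf1, an adaptor of TNF receptors, had 24 minus 6 hour values of 1.16 ± 0.22 (SE, n = 3 arrays per time), Dnah10 0.90 ± 0.20, Parp3 0.77 ± 0.19, Pcdh18 0.83 ± 0.21 and Klf17 0.74 ± 0.19. Diablo, which encodes an antagonist of apoptosis inhibitors, had -0.98 ± 0.20, Nlrp4a -1.04 ± 0.19 (2 arrays at 6 hours) and Mocos -2.44 ± 0.40 (2 arrays at each time). The lysosomal gene Laptm4a had -1.01 ± 0.22 and Sh3bp1 -0.75 ± 0.17. The corresponding values were 0.20 ± 0.26 for Tbx3, 0.45 ± 0.24 for Fos, 0.17 ± 0.18 for Igfbp3 and 0.042 ± 0.22 for Cish. They were -0.41 ± 0.32 for Igf1, 0.34 ± 0.19 for Socs3, 0.0085 ± 0.21 for Ghr, 0.29 ± 0.25 for Bcl6 and -0.25 ± 0.19 for Igfbp5. The mean ratios at the 2 times correlated at r = 0.858 across features, and 554 features passed at both times, all in the same direction. Of these 459 were higher and 95 lower; a feature's tests at both times used 1 residual variance, so they were not independent.

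At the level of lists 4 of 28 differed between the times by camera, although none of their members passed singly or adjusted over the list alone. The chaperones of the endoplasmic reticulum were lower at 24 than at 6 hours (mean difference -0.34, 16 of 18 below 0, adjusted p = 3.37e-05; adjusted p = 0.456 with an estimated correlation), with Hyou1 at -0.70 ± 0.16 and Pdia4 at -0.75 ± 0.25. Hyou1 also belongs to the 7 osteocyte markers, where it passed adjusted over that list alone. The neutrophil markers were lower (-0.46, adjusted p = 0.00832; adjusted p = 0.913 with an estimated correlation), and so was oxidative phosphorylation (-0.13 over 52 genes, adjusted p = 0.00832; adjusted p = 0.913 with an estimated correlation), in which Ndufs1 had -0.79 ± 0.29. The erythroid markers were higher (0.21, 13 of 14 above 0, adjusted p = 0.00831; adjusted p = 0.913 with an estimated correlation), with the anion exchanger gene Slc4a1 at 0.33 ± 0.17. The muscle markers, which varied between arrays beside them, had -0.13 (adjusted p = 0.533), and the other lists had adjusted p between 0.157 and 0.883.

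The calls of 3 of these 4 lists ended without single arrays. The neutrophil difference was -0.12 without replicate 1 (adjusted p = 0.503, with 0.000248 to 0.952 over all alternatives), -0.17 without replicate 4 (0.441), -0.75 without replicate 3 and -0.064 with the scan file prefix as a covariate (0.946), which leaves replicate 5 alone at 24 hours. The erythroid difference was 0.083 without replicate 3 (0.498, with 1.88e-05 to 0.925), 0.14 without replicate 5 (0.285) and 0.33 without replicate 1. Oxidative phosphorylation missed the threshold without replicate 1 (-0.11, 0.0505, with 0.000258 to 0.925), 3 (-0.11, 0.0688), 5 (-0.090, 0.285) or 6 (-0.081, 0.236), and was -0.21 without replicate 4. The muscle list passed without replicate 1 (-0.34, 0.0114) or 4 (-0.34, 0.0154, with up to 0.960 over all alternatives), but was -0.048 without replicate 6, -0.010 without replicate 5 and 0.078 without replicate 3. The glucocorticoid list passed without replicate 1 (0.27, 0.0208, with up to 0.913). Cell cycle (-0.19, 0.00665) and ribosomal genes (-0.18, 0.00470), each with up to 0.999, passed without replicate 3, while without replicate 1 they had 0.13 and 0.080 and without replicate 4 0.071 and 0.015. Without replicate 2 the cell cycle list had 0.017.

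Genes represented by 2 probes from different sequence records, as the platform annotation names them, were compared between those probes. Over 2043 such genes the mean log2 ratios of the 2 probes over both times correlated at r = 0.0286 (95% bootstrap interval -0.0181 to 0.0722), and both probes had 1 sign in 50.4% of genes. The same probes correlated at r = 0.859 between the 6-hour and 24-hour means. Both probes passed over both times for 233 genes, in the same direction for 126 and in opposite directions for 107. The second probe passed for 32.8% of the genes whose first probe passed, and for 34.9% of all these genes. A pass of 1 probe thus did not make a pass of the other more frequent. Tbx3, Cish and Igfbp3 were each measured by a single row, so no second probe could be compared for them. Fos was averaged over 2 rows, whose single values are not given here.

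**Figure D4:**
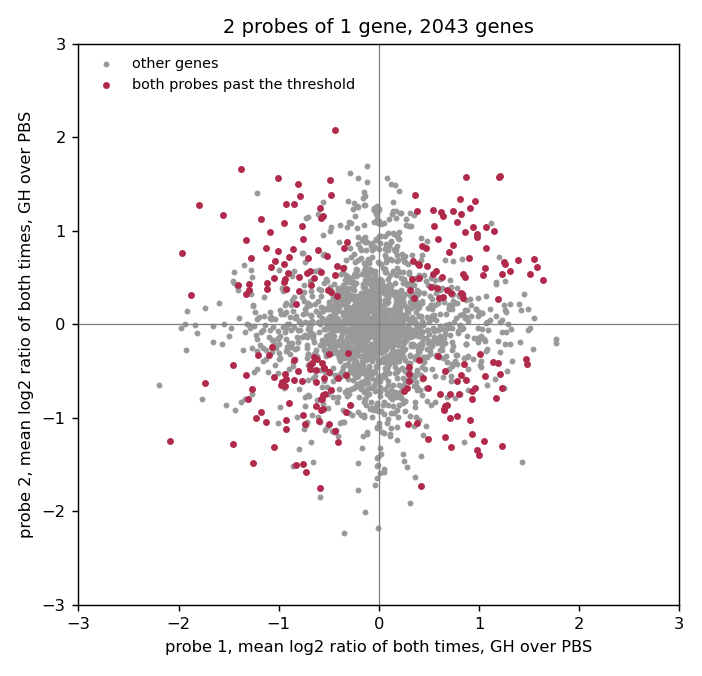
Mean log2 GH over PBS ratio over both times of 1 probe of a gene (horizontal axis) against that of another probe of the same gene from a different sequence record (vertical axis), for 2043 genes; red points mark the 233 genes with both probes past the threshold. The points show no common direction (r = 0.0286).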

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

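The tests of the direction, scatter and slope of replicate 1, those of the lists between the times and the comparison of probe deviations as a test of gene names between arrays were chosen only after the results were seen. The single rows of Igf1 were shown because they disagreed, also a choice made after seeing them.

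Lists stood out here because their GH over PBS ratio differed between 24 and 6 hours in a direct test. The mean differences were -0.34 for chaperones of the endoplasmic reticulum, -0.46 for neutrophil lineage markers, -0.13 for oxidative phosphorylation and 0.21 for erythroid markers, and with an estimated correlation none of the 4 passed (adjusted p = 0.456 for the chaperones and 0.913 for the others).

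The first pattern is that 5914 features passed over both times and 0 between them (506 at an unadjusted p under 0.05 in limma). A dye or hybridization effect specific to each probe could give it, and so could a change in transcript level common to both times. Different probes of a gene would correlate only in the latter case. Over 2043 genes r was 0.0286, while the same probes correlated at 0.859 between the times. Both values met the rule fixed beforehand for a probe-specific effect and against a common change in transcript level. They decide only if the probes' gene names are right, a condition added after the results were seen. Wrong names stay open for most genes. The probes' deviations between arrays, which need not depend on dye, correlated at 0.0338 over all 1737 genes complete for both probes (means 0.0372). They correlated at 0.0909 over the 86 of any list (means 0.208). Over 24 genes (means 0.167) from 7 lists picked for members that moved together, a choice that favours agreement, r was 0.311. Members of these 7 lists had an estimated correlation of at least 0.2, up to 0.603 for muscle markers. This argues against wrong names throughout these lists only, and the other tested lists lay below 0.2. Olfactory and vomeronasal receptor genes, little expressed in bone, were too few to decide: 2 of 5 passed, 1.27 times the share of other named genes (31.4%), and without a dye swap the GH effect and a dye effect on a single probe cannot be told apart.

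The count over both times was set against turned signs of the arrays, a test that a shared dye effect would pass too. Of 32 ways to turn the signs 1 gave as many calls, the real one (5914), the smallest share this test can give. This argues against signs that vary at random between arrays, and says nothing on what made them alike. The highest other way gave 2361. That other way turned replicates 2 to 6 together against replicate 1, so it points to the structure of the arrays. At 6 hours 1 of 4 ways gave as many calls, the real one (603, highest other 0), and at 24 hours 1 of 4 (3444, highest other 0); the ways are too few for a share under 0.05. For the difference 10 of 10 splits of the arrays gave as many calls, since each gave 0 in limma (506 at an unadjusted p under 0.05 in the real split and 309 to 1826 in the others), and 10 splits are too few for a share under 0.05. The split with 1826 sets replicates 1, 2 and 5 against the others and points to a structure of the arrays.

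The second pattern is that replicate 1 stood apart. Its lowest correlation with another array was 0.231, above 0, which argues against a ratio deposited in the opposite direction. Its residual SD around the profile of the other 5 arrays was 0.415, within the 0.362 to 0.523 of those arrays, so its scatter was not larger on the scale deposited. The SD of all its ratios was 0.466, against 0.676 to 0.913 on the others. A larger scatter relative to its own scale therefore stays open. The slope of replicate 1 on the mean of the other arrays was 0.243, against 0.786 to 1.35 for the others. A smaller share of the common profile would give such a slope. The slope follows from the low correlations and small SD that prompted the test, so it is no separate support for that account. Noise added to ratios of an unchanged scale would leave that slope among the others and raise the residual SD, so both values argue against it as the whole account. Noise together with a smaller scale stays open. The planned test by probe pairs decided nothing (r = 0.0492 within replicate 1 and 0.000178 to 0.0529 on the others). No biological explanation was tested, since the labels give replicate 1 no difference from replicates 2 and 3.

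The third pattern is the lower ratio of lists at 24 than at 6 hours, weighed for 2 of the 3 lower lists and not for oxidative phosphorylation. For the neutrophil markers (-0.46) the difference was -0.12 without replicate 1 and -0.17 without replicate 4. The mean of replicate 1 was 0.16, opposite in sign and not only smaller, where the other arrays had -1.59 to -0.60. Its value could account for the difference and stays open, as does that of replicate 4. For the chaperones the difference was -0.24 without replicate 1 and passed by camera (adjusted p = 0.00149, 3.08e-05 to 0.494 over all alternatives). Camera's p measures the spread between genes, not between arrays, so it cannot weigh a single array. The list means on the arrays left were -0.15 and -0.24 at 6 hours and -0.38, -0.40 and -0.50 at 24 hours. These means argue against the value of replicate 1 (0.14) as the whole account, but with only 2 arrays left at 6 hours. The scan file prefix stays open for both lists, since with that covariate the neutrophil difference was -0.064 and the chaperone difference -0.29, which passed (0.0178, within the same range), but the latter sets mainly replicate 5 (-0.40) against 3 arrays that spread from -0.24 to 0.14, and a single array excludes nothing. What stays open is also the time after injection, which the design names and which was not separable from differences between the pools of the 2 times.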

How the results depend on the processing

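The setting with scans of prefix A alone was chosen after seeing the data. No paired analysis was possible because the 2 times share no replicate number. With the scan file prefix as a covariate replicate 5 alone sets the 24-hour ratio of a feature wherever it has a value. Unless a cause is given, the cause was not tested. Of 1146 alternative values of the 68 named gene results past the threshold, 922 stayed past it and 224 kept their direction but missed it. The largest changes were named only if they had the same sign on every array compared, so a kept direction was largely set by that rule. Of 114 alternative values for the 9 list results past the threshold, 76 stayed and 38 kept their direction but missed it. Among values past the threshold as reported or under the alternative, the only change of sign was that of Igf1 at 24 hours, -0.01 as the mean of 3 rows and 1.19 with each probe tested alone, where the row with the smallest p is taken. Of values past it in neither, 35 of named genes and 97 of lists turned direction (for lists, that of the shift against other features). The 6-hour count of 603 became 1782 with arrays scaled to 1 median absolute deviation, 1964 after quantile normalization, 6194 with array weights (3337 higher and 2857 lower, where 486 and 117 are reported; the weights gave replicate 1 a weight of 0.406 and replicate 2 one of 3.26), 1991 at an adjusted p of 0.1 by construction, and 0 with each time fitted alone or with scans of prefix A alone (4287 and 4036 at an unadjusted p under 0.05 in limma); without single replicates it ranged from 0 to 1501. The 24-hour count of 3444 became 32 with the scan file prefix as a covariate, 5950 at an adjusted p of 0.1, 2277 with each time fitted alone, and 0 with scans of prefix A alone (2222 at an unadjusted p under 0.05), which leaves 1 array at 24 hours, assumed to vary like the others; without single replicates it ranged from 0 to 4201. Over both times 5914 became 1393 with the prefix, 333 with prefix A alone and 3685 with a fold of at least 1.5; without single replicates it ranged from 2192 to 6756. The difference of 0 became 2 with the prefix and was 0 under every other alternative in limma (321 to 895 at an unadjusted p under 0.05), leave-one-out included. Of 2 lists at 6 hours 1 remained with prefix A alone and 0 passed with an estimated correlation; without single replicates 0 to 5 passed. Of 3 at 24 hours 0 passed with the prefix, with prefix A alone or with an estimated correlation, and 2 to 4 without single replicates. Of 4 in the difference 2 passed with array weights and 0 with an estimated correlation or fry, and 2 to 4 without single replicates. Fry asks whether a list moves 1 way, not whether it differs from other genes. Features measured on few arrays left the test when an array was left out, which gave no value for them, and the T-box list was not tested without replicate 1, 2, 3, 4 or 6 or with prefix A alone. Signal over background was not known.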

Other observations

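The relation between muscle and neutrophil lists was tested only after its values were seen.

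Further lists held genes past the threshold over both times, where 35.5% of all features passed. The member counts in this and the next paragraph were not tested against that share. Of 11 clock genes 2 rose and 3 fell (3 and 5 adjusted over the list alone): Npas2 (0.45 ± 0.07, SE, n = 6 arrays, adjusted p = 0.00840) and Cry1 (0.45 ± 0.13, 0.0402) rose, and Rora (-0.75 ± 0.15, 0.0128) and Arntl, which encodes the clock activator BMAL1 (-1.11 ± 0.29, 0.0292), fell. Of 17 interferon response genes 1 rose, Mx2 (0.88 ± 0.14, n = 4), and 5 fell, among them Oas1a (-0.81 ± 0.17), Ifi204 (-0.57 ± 0.12) and the immunoproteasome gene Psmb8 (-0.91 ± 0.20), with the same numbers adjusted over the list alone. Neither list shifted as a whole at 6 hours (adjusted p = 0.812 and 0.312) or at 24 hours (0.523 and 0.498).

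Of 13 cholesterol synthesis genes Dhcr7 (0.42 ± 0.09) and Lss (0.59 ± 0.12) rose and the sterol transfer gene Stard4 (-0.61 ± 0.10) fell over both times, with the same numbers adjusted over the list alone. Of 14 amino-acid response genes Sesn2 (0.43 ± 0.10), Ddit4 (1.09 ± 0.28) and Shmt2 (0.61 ± 0.18) rose, and 0 did when adjusted over the list alone. Of the 4 chondrocyte markers measured, which were too few for a list test, Col9a3 (0.87 ± 0.13) and Fgfr3 (0.34 ± 0.09) rose and Hapln1 (-0.95 ± 0.17) and Col2a1 (-0.67 ± 0.15) fell, also when adjusted over the list alone. Of the 4 megakaryocyte markers Selp (0.97 ± 0.12) rose and Rab27b (-0.42 ± 0.11) fell, and of the 4 T and NK markers Cd28 (1.32 ± 0.21) and Cd3e (0.41 ± 0.09) rose, again with the same numbers adjusted over the list alone. Of the 4 STAT5-induced targets Cish rose and Igf1, Bcl2l1 (0.08 ± 0.08) and Socs3 did not pass, with 1 adjusted over the list alone.

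Mean muscle and neutrophil ratios varied between arrays in opposite directions. In replicate order the muscle means were 0.09, 0.47, 0.92, 0.78, 0.11 and 0.18, and the neutrophil means 0.16, -0.66, -1.11, -1.59, -0.60 and -0.81. Over the 6 arrays r was -0.776 (exact permutation p = 0.0569) and rho -0.886 (exact permutation p = 0.0333). This is 1 of 378 possible pairs of tested lists, and neither p was adjusted over them. Without replicates 3 and 4, the arrays farthest from the median muscle mean, r was -0.457 over 4 arrays, which was not tested, and the 4 scans of prefix A and the 2 of prefix B are too few for a value within each.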
